A study of Mus musculus with 13 samples.

How the data were processed

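The starting point was a table of raw counts per gene and library, deposited by the authors for 56,953 Ensembl genes and 13 libraries. Per the submitters' processing notes, non-stranded poly-A libraries of aorta RNA were sequenced on a DNBseq instrument, aligned with STAR 2.6.1d to the mouse build GRCm39 and counted with featureCounts of Subread 1.6.3. The counts were whole numbers and were used without further rounding or scaling. Genes are named by symbol and Ensembl identifier; 1,554 genes of the table had no symbol. Genomic positions are not used here, since the annotation at hand was for another build than the one the counts were made on. No pair of libraries had the same counts, and the closest pair differed by a chi-squared statistic of 18.9 per degree of freedom.

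Genes with low counts were removed with the filterByExpr function of edgeR over the 4 groups, which left 18,055 genes holding 99.9% of the counts in each library. Libraries were scaled with TMM factors, and CPM values below are those of edgeR at the TMM-scaled library size. Each gene was fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group, and the 7 group contrasts were tested two-sided. The effect of each drug over the whole layout came from an additive model with auranofin given or not and atorvastatin given or not. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Each log2 fold change is given with a standard error (SE), computed as its size divided by the square root of the F statistic, and each mean CPM with its SD. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run as other tools. Alternatives were median-of-ratios size factors, no low-count filter, a stricter filter (a CPM of at least 1 in at least 2 libraries), the compared groups alone, the replicate number as block, an adipocyte score as covariate, an adjusted p under 0.1, and leaving out each library in turn.

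The models, comparisons, 32 gene lists, 23 panel genes and rule for named genes were fixed before the data were examined. The lists held cell type markers and pathways and covered 501 tested genes. They were tested with camera of limma on voom values, with a preset correlation of 0.01 between genes, two-sided and adjusted with the Benjamini-Hochberg method over the 32 lists of a comparison. The same test with an estimated correlation, the fry test, and an exact permutation of the mean log2 CPM of each list were run beside it. Up or down counts of list members are counts of fitted signs in edgeR, not of tests.

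The rule for named genes took, per comparison and direction, up to 12 genes past an adjusted p of 0.05. Where fewer than 5 passed, it took the 3 genes with the smallest p as genes that did not pass, among those with a mean log2 CPM of at least 0 and a symbol other than a predicted gene, a clone name or an immunoglobulin or T cell receptor segment. Panel genes were reported in the comparisons with the Western diet group whether or not they passed. For each list, up to 4 members with the smallest p in the direction of its test could be named. Genes named outside this rule are said to have been chosen after their values were seen.

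The pipeline was tried on simulated counts with the spread of this series and 200 genes changed by a known factor. For auranofin against Western diet it recovered 0.5% of genes changed 2-fold, 67.5% of those changed 4-fold and 84% of those changed 8-fold. For the combination against Western diet these shares were 0%, 58% and 81.5%, and for the auranofin term of the additive model they were 25%, 78% and 91.5%. The simulated genes were drawn independently of each other, so structure shared by the genes of a library was left out. These shares need not hold for the real data. Figures were drawn with matplotlib 3.10.9.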

Results

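The series measured RNA of whole aorta from mice lacking apolipoprotein E, a strain that develops atherosclerosis, all fed a Western diet (WD) for 16 weeks from 6 weeks of age. Mice were randomized to the diet alone (WD, 5 libraries), to auranofin at 3 mg/kg/day (3 libraries), to atorvastatin at 10 mg/kg/day in the diet (3 libraries), or to both drugs (combination, 2 libraries). Auranofin is a gold compound used in rheumatoid arthritis that inhibits thioredoxin reductase, and atorvastatin is a statin, a drug that lowers cholesterol. The question put by the study was whether auranofin affects the progression of atherosclerosis. The 13 libraries held 19,703,683 to 26,079,566 counts, with a median of 23,550,042, and 22,432 to 25,464 genes with a count. Totals ran from 22,219,720 to 26,079,566 in WD, from 23,550,042 to 24,156,822 with auranofin and from 22,232,290 to 23,766,975 with atorvastatin, and were 22,932,778 and 19,703,683 with the combination. Mitochondrial genes took 9.36% to 38.8% of counts, with group means of 18.7% (SD 7.29) for WD, 26.3% (SD 11.5) for auranofin, 16.1% (SD 4.54) for atorvastatin and 15.2% (SD 5.49) for the combination. The labels gave no batch and did not tie each library to a named mouse, so the p-values below measure only the spread between these samples.

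Apoe (ENSMUSG00000002985), the gene disrupted in this strain, had 152 to 489 counts per library, a mean of 13.97 ± 4.46 CPM (SD, n = 5) in WD and 16.3 ± 9.45 (n = 3) with auranofin. No wild-type aorta was analysed here, so these values are not a check of the genotype. The WD aortas themselves differed widely in macrophage transcripts. Cd68, a lysosomal protein of macrophages, ran from 18.5 to 350 CPM across the 5 WD libraries, and Spp1, osteopontin, an abundant secreted protein of foamy macrophages, from 131 to 2787 CPM. WD 3 and WD 5 held the low values of both genes, at 18.5 and 25.5 CPM for Cd68 and 134 and 131 CPM for Spp1.

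**Figure D1:**
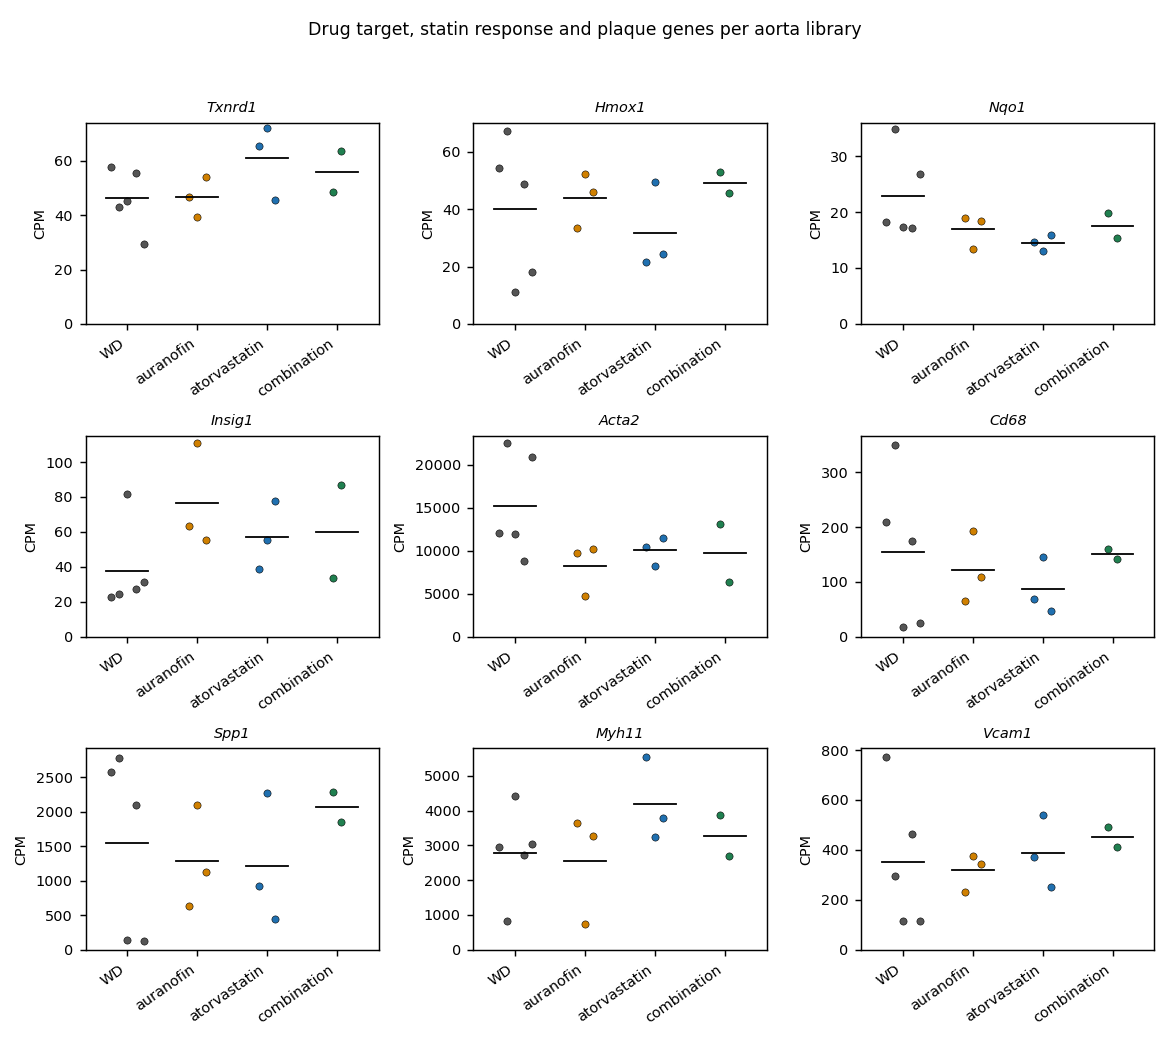
CPM of 9 genes of the drug targets, the statin response and plaque in each of the 13 aorta libraries, by group; points are libraries and bars are group means. Within WD, Cd68 ran from 18.5 to 350 CPM and Spp1 from 131 to 2787 CPM.

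Auranofin alone was compared with WD to ask what the drug changed in the atherosclerotic aorta. Genes of brown adipocytes, B cells and T cells rose together as lists in the auranofin group, and genes of the extracellular matrix and of contractile smooth muscle cells fell (camera; for each list the adjusted p = 0.519 with an estimated correlation). Much of this lay in 1 library: without auranofin 2 the mean log2 fold change of B cell genes was 0.54, of matrix genes −0.11 and of contractile smooth muscle genes 0.04, and these 3 lists no longer passed. The mean log2 fold change was 1.44 for brown adipocyte genes, with 12 of 12 members higher, and it was led by Ppargc1a, a coactivator of mitochondrial biogenesis, at 1.75 (SE 0.51), and Ucp1, the uncoupling protein of brown fat, at 2.02 (SE 0.77). B cell genes had a mean of 1.46 with 14 of 14 higher, among them Ighm, the IgM heavy chain, at 2.75 (SE 0.80). Matrix genes had a mean of −0.44 with 23 of 24 lower, such as Col1a1, a chain of type I collagen, at −0.71 (SE 0.25) and Loxl1, which crosslinks elastin, at −0.82 (SE 0.30). These values compared 3 auranofin with 5 WD libraries, and none of the members named passed over all genes.

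By camera with the preset correlation, 15 of 32 lists passed between auranofin and WD, 11 higher and 4 lower; none passed with an estimated correlation, where the smallest adjusted p = 0.519 with an estimated correlation. The camera adjusted p was 4.83e-07 for brown adipocytes, 2.06e-06 for fatty acid synthesis (mean log2 fold change 0.97), 3.47e-06 for B cells, 3.59e-06 for T cells (1.06), 3.54e-05 for adipocytes in general (0.85) and 6.37e-05 for endothelial cells (0.52). For each of these lists the adjusted p = 0.519 with an estimated correlation. The erythroid list followed at 0.00159 (1.00) and neutrophils at 0.00541 (0.98), again with an adjusted p = 0.519 with an estimated correlation. Without auranofin 2 the mean was 0.61 for the erythroid list (adjusted p 0.139), 0.47 for neutrophils (0.294) and 0.29 for foamy macrophages (0.557). Interferon-stimulated genes had a mean of 0.22 and an adjusted p of 0.00981, and foamy macrophages a mean of 0.65 and 0.0112; both had an adjusted p = 0.792 with an estimated correlation. Without auranofin 2 the mean of interferon-stimulated genes was −0.09. For foamy macrophages the sign differed by method, as edgeR fitted 7 members higher and 8 lower while 13 of 15 were higher in voom. Their score was 7.64 to 8.84 with auranofin. It was 8.39, 8.51 and 8.48 in WD 1, WD 2 and WD 4, but 6.40 in WD 3 and 5.93 in WD 5. Oxidative phosphorylation passed at 0.0131 (0.22; adjusted p = 0.838 with an estimated correlation), and its mean was −0.07 without auranofin 2. The lists that fell were the matrix at 5.56e-06, contractile smooth muscle cells at 0.000412 (−0.59), immediate early genes at 0.00129 (−0.42) and cell cycle at 0.0176 (−0.27). With an estimated correlation their adjusted p was 0.519 for the first 3 and 0.838 for cell cycle. No member passed over all genes in any list, and adjusted over the list alone 5 B cell genes and 1 interferon-stimulated gene did.

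The T cell score (mean log2 CPM) was 0.97 in auranofin 1 and 1.88 in auranofin 2, and −0.19 in auranofin 3, within the WD range of −0.82 to 0.52. Auranofin 1 also held Rag1, a recombinase of immature lymphocytes, at 6.67 CPM, against 4.05 in WD 3 and at most 0.263 elsewhere. All 14 T cell genes were fitted higher, including Cd3e, part of the T cell receptor complex, at 1.45 (SE 0.62) and Cd28, a costimulatory receptor, at 1.03 (SE 0.50). Endothelial genes included Pecam1, a junction protein, at 1.02 (SE 0.36) and Tek, the angiopoietin receptor, at 1.11 (SE 0.40), and fatty acid synthesis included Gpam, the first enzyme of triglyceride assembly, at 1.19 (SE 0.46). Among the smooth muscle genes Tagln was at −0.87 (SE 0.39) and Cnn1 at −0.89 (SE 0.41), both actin-binding proteins of the contractile state, and among immediate early genes Zfp36, which destabilizes cytokine mRNAs, was at −0.67 (SE 0.28) and Egr1 at −0.64 (SE 0.30). Rsad2, the antiviral protein viperin, was the interferon-stimulated gene that passed adjusted over the list alone, at 0.98 (SE 0.25), with 13.2 ± 4.19 CPM (SD, n = 3) against 6.71 ± 1.58 (n = 5). The share of mitochondrial counts was highest in auranofin 2, at 38.8%, and the same library had the lowest TMM factor, 0.629, the most Ucp1, 1817 CPM, and the most Igkc, an antibody light chain, 707 CPM. Leaving out auranofin 2 left 7 lists past camera, of which 6 were among the 15: brown adipocytes (1.06), adipocytes (0.68), fatty acid synthesis (0.72), T cells (0.62), immediate early genes (−0.44) and cell cycle (−0.34). Without that library endothelial genes had a mean of 0.09. Of the 15 calls, 13 were kept without WD 1 and 13 without WD 4, 12 without WD 3, and 14 without each of WD 2, WD 5, auranofin 1 and auranofin 3. Exact two-sided permutation of the list scores gave a smallest p of 0.0714, where 0.0179 was the smallest possible.

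At the level of RNA, the targets and responses that auranofin is known for did not pass. The activity of thioredoxin reductase, which the drug inhibits, was not measured here. Txnrd1, thioredoxin reductase 1, had a log2 fold change of 0.01 (SE 0.24), Hmox1, heme oxygenase 1, 0.14 (SE 0.49; adjusted p 0.939) and Nqo1, a quinone reductase induced by NRF2, −0.43 (SE 0.26). The camera adjusted p was 0.861 for NRF2 targets, 0.319 for selenoproteins and the thioredoxin system, 0.438 for the metal response, 0.436 for the heat shock response and 0.319 for the unfolded protein and integrated stress response. NF-kB inflammatory genes had an adjusted p of 0.727, MHC class II presentation 0.727, macrophages 0.279, resident adventitial macrophages 0.861, LXR targets 0.113, cholesterol synthesis 0.533 and the circadian clock 0.0829. Modulated smooth muscle cells had 0.216, cartilage and calcification genes 0.533, adventitial fibroblasts 0.861, Schwann cells and nerve 0.861, and striated muscle 0.295. Signs were mixed in several of these: the cholesterol list had a mean of 0.07 and a median of −0.02, MHC class II 0.12 and −0.04, and NRF2 targets a lower direction in camera with a median of 0.04. Macrophage genes were mostly lower in edgeR, 11 of 16, while camera gave the list as higher. Cd68 was at −0.35 (SE 0.78), Spp1 at −0.27 (SE 0.92), Il1b, an inflammatory cytokine, at 0.49 (SE 1.10), and Acta2, smooth muscle actin, at −0.89 (SE 0.45).

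No single gene passed between auranofin and WD in edgeR (0 of 18,055 at a Benjamini-Hochberg adjusted p under 0.05, smallest 0.671). An unadjusted p under 0.05 was found for 1173 genes, 489 higher and 684 lower. A share of 0.05 of the genes tested is 903, but other splits of the same libraries gave a median of 1045. Of 56 splits, the real one included, 25 reached 1173. DESeq2 passed 2 genes, Foxs1 at −1.83 and Ighg2c, an antibody heavy chain, at 6.61, and limma passed 0. Foxs1 (ENSMUSG00000074676), a forkhead transcription factor, had an edgeR log2 fold change of −1.82 (SE 0.39; adjusted p 0.671), with 7.08 ± 3.33 CPM (SD, n = 3) against 25.3 ± 10.4 (n = 5). Bik, a pro-apoptotic protein, was at −1.36 (SE 0.34). Of the genes with the smallest p among those higher, Jchain, the joining chain of IgA and IgM, was at 5.82 (SE 1.26), but 1 library, auranofin 2, held 134 CPM and no other held more than 3.23. Rsad2 and Zfp366, at 1.55 (SE 0.40), were the other two. The unadjusted count was 378 without auranofin 2, 662 without auranofin 1, 715 without WD 5, 1854 without WD 3 and 2130 without WD 4.

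**Figure D2:**
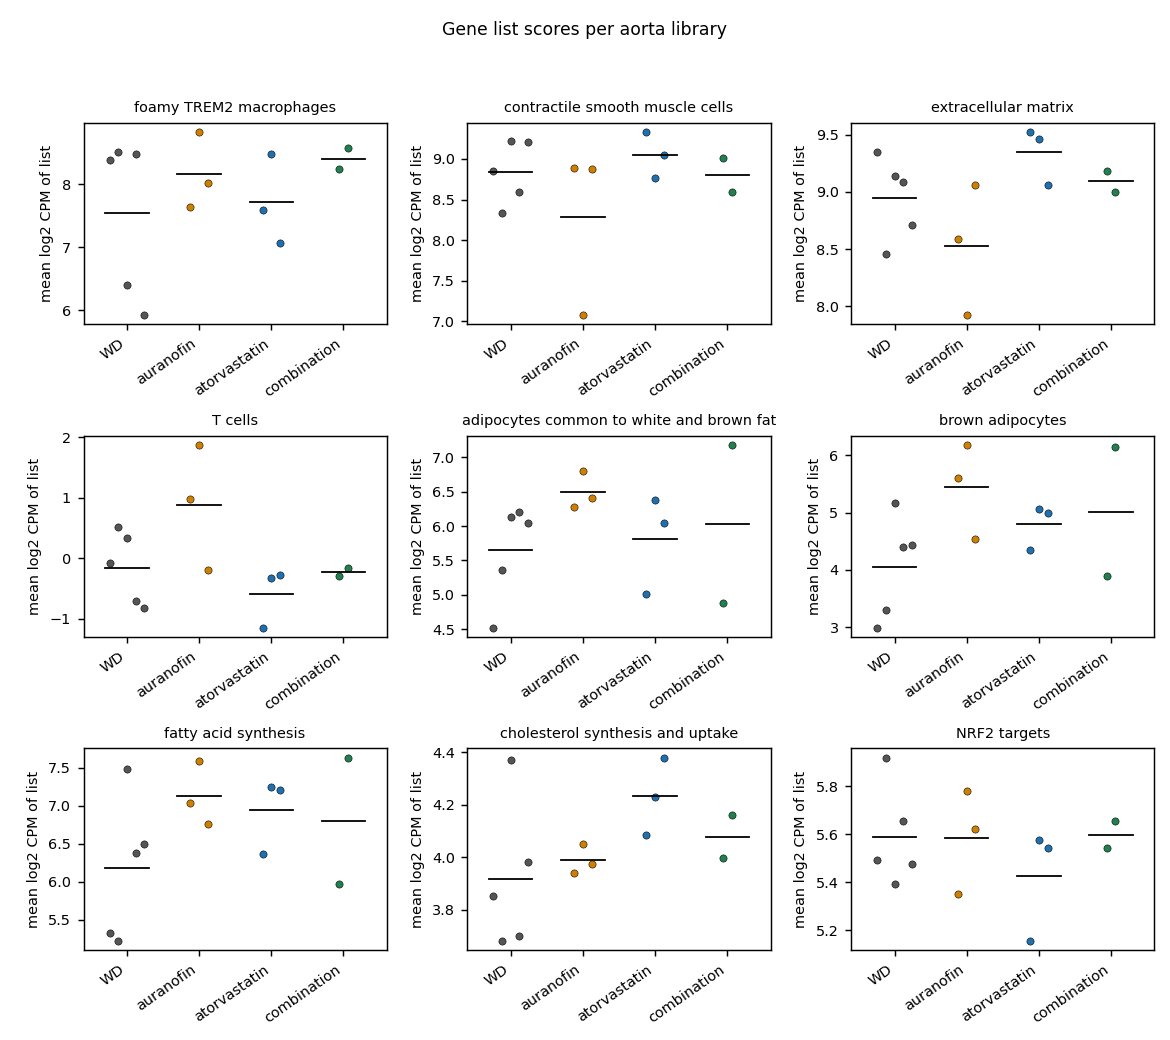
Mean log2 CPM of the members of 9 gene lists in each of the 13 aorta libraries, by group; points are libraries and bars are group means. The auranofin mean for brown adipocytes was 5.45 against 4.06 in WD, with single libraries of the groups overlapping.

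Atorvastatin alone was compared with WD as the known lipid-lowering treatment. Genes of cholesterol synthesis and uptake rose as a list, with a mean log2 fold change of 0.31 and 16 of 23 members higher (camera; adjusted p = 0.976 with an estimated correlation). Cyp51 and Idi1, both enzymes of the pathway, were at 0.58 (SE 0.23) and 0.62 (SE 0.26). Genes of resident adventitial macrophages fell, with a mean of −0.69 and 10 of 10 members lower, such as Pf4, a chemokine, at −1.62 (SE 0.52); the adjusted p = 0.976 with an estimated correlation here too.

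By camera 8 of 32 lists passed between atorvastatin and WD, 3 higher and 5 lower, and none passed with an estimated correlation: the adjusted p = 0.976 with an estimated correlation for all 8. The lists that rose were cholesterol synthesis at 0.0153, fatty acid synthesis (mean 0.76) at 0.0113 and the extracellular matrix (0.42) at 0.0153. The matrix score was 8.46 in WD 2 and 8.71 in WD 5 but 9.08 to 9.35 in the other WD libraries, against 9.06 to 9.53 with atorvastatin. Matrix genes included Fn1, fibronectin, at 0.86 (SE 0.40) and Col5a1, a type V collagen chain, at 0.65 (SE 0.32), with 21 of 24 members higher. Those that fell were selenoproteins and the thioredoxin system (−0.42) at 0.0105, resident adventitial macrophages at 0.0153, adventitial fibroblasts (−0.32) at 0.0268, striated muscle (−1.75) at 0.0268 and oxidative phosphorylation (−0.30) at 0.0276. The selenoprotein score was 7.09 in WD 2 and 6.74 in WD 5, but 6.27 to 6.33 in the other WD libraries, against 5.90 to 6.32 with atorvastatin. Oxidative phosphorylation was likewise highest among the WD libraries in WD 2 (7.29) and WD 5 (7.09), the 2 with the lowest TMM factors of that group (0.639 and 0.801) and the highest mitochondrial shares (26.9% and 24.2%). Among these, Msrb1, a selenoprotein that reduces methionine sulfoxide, was at −1.14 (SE 0.40), Prdx2, a peroxiredoxin, at −0.98 (SE 0.36), and Pi16, a marker of adventitial fibroblasts, at −0.70 (SE 0.28). Actc1, cardiac actin, was at −4.13 (SE 1.53), and Myl2, a heart muscle transcript, stood at 58.6 CPM in WD 1 and 70.8 in WD 4 with a median of 0.454 over all libraries. Without WD 4 the lists past camera were 4, all among the 8: selenoproteins, fatty acid synthesis, matrix and oxidative phosphorylation. The number of the 8 calls kept was 6 without WD 1, 6 without WD 2, 5 without WD 3, 7 without WD 5, 7 without atorvastatin 1, 7 without atorvastatin 2 and 6 without atorvastatin 3. Exact two-sided permutation of the list scores gave a smallest p of 0.0714 here as well.

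No gene passed between atorvastatin and WD in edgeR (0 at a Benjamini-Hochberg adjusted p under 0.05; smallest 0.340), in DESeq2 (0) or in limma (0), while 2648 had an unadjusted p under 0.05 in edgeR, 756 higher and 1892 lower. The genes with the smallest p were Slc6a2, the noradrenaline transporter of sympathetic neurons, at 3.12 (SE 0.74), Nhsl2 at 0.86 (SE 0.23) and Spen, a transcriptional repressor, at 1.18 (SE 0.33), and among those lower Fhl2, a LIM protein of muscle, at −1.20 (SE 0.31), Tango2 at −0.72 (SE 0.19) and Apod, a lipocalin, at −0.86 (SE 0.25), all with an adjusted p of 0.340. Atorvastatin 2 held 40.6 CPM of Slc6a2 and no other library more than 3.02. Among nerve genes adjusted over the list alone 1 passed, Ngfr, the low-affinity nerve growth factor receptor, at 3.83 (SE 0.83), with 14.5 CPM in atorvastatin 2 and at most 0.966 elsewhere, though the list itself did not (camera adjusted p 0.388). Cd68 was at −0.83 (SE 0.80), Spp1 at −0.35 (SE 0.92) and Nqo1 at −0.65 (SE 0.26). The unadjusted count was 327 without atorvastatin 1, 660 without atorvastatin 2, 1136 without WD 2, 1289 without WD 5 and 4169 without WD 3.

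The combination was compared with WD to ask what both drugs given together changed. Genes of brown adipocytes rose as a list, with a mean log2 fold change of 1.01 and 12 of 12 higher, and so did those of fatty acid synthesis (0.64, 15 of 17), foamy macrophages (0.87, 13 of 15) and erythroid cells (0.90); for each the adjusted p = 0.977 with an estimated correlation. Lpl, lipoprotein lipase, was at 1.07 (SE 0.51) and Cd36, a scavenger receptor for fatty acids and lipoproteins, at 0.90 (SE 0.55). Both are also adipocyte genes and were high in combination 2 alone of the pair, with Lpl at 1621 CPM against 473 in combination 1 and Cd36 at 503 against 108, as was the general adipocyte score, 7.19 against 4.89. In contrast, Spp1 was at 0.42 (SE 1.02) and Cd68 at −0.04 (SE 0.89). The camera adjusted p was 0.000349, 0.00113, 0.00316 and 0.00336 in that order. For the erythroid list edgeR fitted 4 members higher and 4 lower, while voom had 8 of 8 higher; Slc4a1, the anion exchanger of red cells, was at 1.80 (SE 0.67). The brown adipocyte score was 6.14 in combination 2 and 3.89 in combination 1, against 2.99 to 5.17 in WD. The foamy macrophage score was 8.24 in combination 1 and 8.57 in combination 2. It was 8.39, 8.51 and 8.48 in WD 1, WD 2 and WD 4, and only WD 3 (6.40) and WD 5 (5.93) stood clearly lower. Without combination 2 brown adipocytes had a mean of −0.11 and fatty acid synthesis −0.21, and 1 of the 4 calls was kept among 12 lists. The number of lists past camera was 7 without WD 1, 13 without WD 2, 4 without WD 3, 8 without WD 4, 8 without WD 5 and 8 without combination 1, of which 2, 4, 2, 4, 3 and 3 were among the original 4.

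No gene passed in the combination in edgeR (0 at a Benjamini-Hochberg adjusted p under 0.05; smallest 0.915) or limma (0), and 265 had an unadjusted p under 0.05. DESeq2 passed 4 genes, Sbk3, Cacna2d2, Hcn4 and Myl4, of which Hcn4, a pacemaker channel of the heart, had 15.7 CPM in combination 2 and at most 0.438 elsewhere. In edgeR Myl4, the atrial myosin light chain, was at 3.99 (SE 0.82), and combination 2 held 217 CPM of it against at most 12.8 in any other library. Itga2b, the platelet integrin, was at 2.00 (SE 0.40), with 25.7 CPM in combination 1 and at most 7.32 elsewhere. Cd226, a receptor of T and NK cells, was at 1.96 (SE 0.50). It had 5.03 CPM in combination 1 and 1.51 in combination 2, against 0.507 to 1.11 in WD. The T cell score of combination 1 was −0.30, within the WD range of −0.82 to 0.52. Foxs1 was at −1.39 (SE 0.44), with 9.62 ± 0.425 CPM (SD, n = 2), Bik at −1.02 (SE 0.39) and Acta1, skeletal muscle actin, at −5.09 (SE 1.86). In the striated muscle list 2 genes passed adjusted over the list alone, although camera gave 0.839, a mean of −0.09 and a median of −0.79. Leaving out combination 1 gave 10 genes past the threshold and 823 at an unadjusted p under 0.05, with the lone library assumed to vary like the other groups. The unadjusted count was 118 without combination 2, 614 without WD 3 and 545 without WD 4.

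Each drug was also set against the other and against the combination. Between auranofin and atorvastatin the genes with the smallest p included Col1a1, at −1.06 (SE 0.27) with 603 ± 160 CPM (SD, n = 3) against 1254 ± 266 (n = 3), and Creb3l1, a transcription factor that drives collagen production, at −0.83 (SE 0.17). Plec, plectin, was at −0.74 (SE 0.19), and Lrrn4cl at 1.55 (SE 0.33), Dact2 at 1.45 (SE 0.34) and Ackr4, a scavenging chemokine receptor, at 1.92 (SE 0.46). None passed in edgeR (0 genes; smallest adjusted p 0.826; 795 at an unadjusted p under 0.05) or limma (0). DESeq2 passed 5: Creb3l1, Col1a1, Plec, Lrrn4cl and BB365896. Camera passed 20 of 32 lists in this contrast, while 0 passed with an estimated correlation (smallest adjusted p = 0.537 with an estimated correlation). The unadjusted count was 142 without auranofin 2, 1600 without auranofin 3, 246 without atorvastatin 1 and 408 without atorvastatin 2. Against atorvastatin, the combination had Myl4 at 5.30 (SE 1.05), Itga2b at 2.04 (SE 0.46), Slc6a2 at −2.95 (SE 1.04), Apol7b at −1.21 (SE 0.44) and Napb at −0.99 (SE 0.36). Against auranofin it had Myl4 at 4.89 (SE 1.03), Itga2b at 2.02 (SE 0.46), Gpc1, a heparan sulfate proteoglycan, at 1.29 (SE 0.31), Dact2 at −1.40 (SE 0.39), Ackr4 at −1.71 (SE 0.53) and Wnt10b at −1.21 (SE 0.40). In these contrasts edgeR passed 0 genes, with 237 and 359 at an unadjusted p under 0.05, limma 0 and DESeq2 5 and 3. Without combination 1 edgeR passed 8 in each, with 479 at an unadjusted p under 0.05 in the first. Against atorvastatin the unadjusted count was 146 without atorvastatin 1, and against auranofin it was 147 without auranofin 2 and 839 without auranofin 3.

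Over the whole layout, auranofin was given to 5 and withheld from 8 of the 13 aortas. In the additive model T cell genes rose with auranofin (mean log2 fold change 0.85, 14 of 14 higher), as did brown adipocyte (0.95), erythroid (0.95), neutrophil (0.94) and foamy macrophage genes (0.67, 14 of 15), and matrix (−0.37, 23 of 24 lower), contractile smooth muscle (−0.47) and immediate early genes (−0.30) fell; for each of these the adjusted p = 0.341 with an estimated correlation. By camera 18 lists passed, 14 higher and 4 lower, and none with an estimated correlation, where the smallest adjusted p = 0.341 with an estimated correlation. These were the 15 of auranofin against WD together with macrophages (0.40; adjusted p 0.00222, and 0.560 with an estimated correlation), LXR targets (0.30; 0.00239, and adjusted p = 0.341 with an estimated correlation) and the circadian clock (0.19; 0.0176, and adjusted p = 0.341 with an estimated correlation). The lowest foamy macrophage scores, 5.93 in WD 5 and 6.40 in WD 3, stood on the side without auranofin. The T cell score was above the WD range of −0.82 to 0.52 only in auranofin 1 (0.97) and auranofin 2 (1.88). Auranofin 3 (−0.19), combination 1 (−0.30) and combination 2 (−0.17) lay within that range. With atorvastatin alone it ran from −1.15 to −0.28. Adjusted over the list alone 2 erythroid genes passed. Car2, a carbonic anhydrase, was at 1.25 (SE 0.31), Il15ra, the interleukin 15 receptor, at 0.65 (SE 0.17) and Cd226, highest in combination 1, at 1.40 (SE 0.36). Foxs1 was at −1.36 (SE 0.33), Creb3l1 at −0.51 (SE 0.12) and Rasl11a at −0.94 (SE 0.25). Of single genes edgeR passed 0 (smallest adjusted p 0.998; 486 at an unadjusted p under 0.05), DESeq2 0 and limma 0. Without auranofin 2 the 18 lists became 12, and the unadjusted count was 164, against 276 without WD 1 and 1436 without combination 1.

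Atorvastatin was likewise given to 5 of the 13 aortas. Over the layout, by camera with the preset correlation only, matrix genes rose (0.49, 23 of 24 higher). So did those of cartilage and calcification (0.93), modulated smooth muscle cells (0.59) and cholesterol synthesis (0.23). The lowest matrix scores, in auranofin 2 (7.92), WD 2 (8.46), auranofin 1 (8.59) and WD 5 (8.71), stood on the side without atorvastatin. The cartilage score was 4.58, 5.53 and 2.17 in atorvastatin 1, 2 and 3, and 3.41 and 4.37 in the combination. It ran from 1.84 to 5.20 in WD and from 2.23 to 3.79 with auranofin. T cell genes fell (−0.76, 14 of 14 lower), as did resident adventitial macrophages (−0.49), adventitial fibroblasts (−0.24), selenoproteins (−0.27) and oxidative phosphorylation (−0.25). The T cell scores of 0.97 in auranofin 1 and 1.88 in auranofin 2 were the 2 highest of the 13 and stood on the side without atorvastatin. The group mean was −0.59 with atorvastatin and −0.23 with the combination, against −0.15 in WD, and the T cell list was not among those that passed between atorvastatin and WD. Without auranofin 2 its mean log2 fold change for the term was −0.55. With an estimated correlation the adjusted p was 0.979 for cartilage, modulated smooth muscle and oxidative phosphorylation and 0.931 for the rest. Camera passed these 9 lists, with adjusted p from 4.88e-07 for the matrix to 0.0256 for modulated smooth muscle cells. Adjusted over the list alone 2 cholesterol genes passed, and 1 T cell gene, Trbc2, at −1.96 (SE 0.52), and 1 resident macrophage gene, Timd4, at −0.97 (SE 0.29). Irs2, an insulin receptor substrate, was at 1.08 (SE 0.29), with 51.8 ± 8.76 CPM (SD, n = 3) on atorvastatin alone and 24.1 ± 13.1 (n = 5) in WD. Spata2 was at 0.45 (SE 0.12), Lrrn4cl at −0.84 (SE 0.23), Dact2 at −0.91 (SE 0.26) and Lurap1l at −0.60 (SE 0.17). Of single genes edgeR passed 0 (smallest adjusted p 0.546; 1278 at an unadjusted p under 0.05), DESeq2 0 and limma 0. The unadjusted count was 353 without atorvastatin 1, 412 without atorvastatin 2, 563 without auranofin 2, 724 without WD 5, 1987 without auranofin 3, 2062 without WD 3 and 2403 without combination 1.

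The interaction asked whether the effect of the combination differed from the sum of the drugs. Lists of fatty acid synthesis (−1.09), endothelial cells (−0.62), brown adipocytes (−1.22) and B cells (−1.39) were lower in the combination than that sum, and striated muscle (2.48) was higher. The camera adjusted p was 0.00127, 0.00400, 0.00608, 0.00608 and 0.0175, and for all 5 the adjusted p = 0.958 with an estimated correlation. In striated muscle 7 members passed adjusted over the list alone, such as Myl4 at 6.20 (SE 1.32). Of single genes edgeR passed 0 (smallest adjusted p 0.791; 559 at an unadjusted p under 0.05), limma 0 and DESeq2 11, among them Myh6, Myh7, Tnnt2, Actc1 and Myl4 of heart muscle. Fhl2 was at 2.13 (SE 0.48), Tnnc1, cardiac troponin C, at 9.62 (SE 2.22), Ppat at −0.83 (SE 0.26), Zfp366 at −2.08 (SE 0.66) and Jchain at −6.49 (SE 2.13). The interaction counts WD and the combination on the same side, and heart transcripts lay in single libraries of both. Myh6 was at 625 CPM in combination 2, 162 in WD 4 and 96.5 in WD 1, and at most 7.95 elsewhere. Tnnc1 had 9.32 CPM (SD 12.2) in WD and 19.1 (SD 24.8) in the combination. Jchain had 134 CPM in auranofin 2 and at most 3.23 elsewhere. Without auranofin 2 none of the 5 lists was kept, and 4, 4, 3, 3 and 3 were kept without WD 3, auranofin 1, atorvastatin 3, combination 1 and combination 2. The lists past camera were 8 without WD 2, 10 without auranofin 3 and 9 without atorvastatin 1. Without combination 1 edgeR passed 2 genes. The unadjusted count was 1029 without WD 3, 1175 without WD 4, 371 without auranofin 1, 285 without atorvastatin 1, 357 without atorvastatin 2, 324 without combination 1 and 984 without combination 2.

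The 3 comparisons with WD shared the same 5 control libraries, and no gene was called in any of them by edgeR (0 shared calls). Across 18,055 genes, which are not independent replicates, the log2 fold changes of auranofin and atorvastatin correlated at r = 0.536, those of auranofin and the combination at 0.494 and those of atorvastatin and the combination at 0.659. With no change in any group, 20 simulations gave 0.376, 0.323 and 0.329 from the shared controls alone. The covariances were 0.146, 0.109 and 0.173 against 0.0728, 0.0720 and 0.0725 in the simulations. Over 1000 relabellings of the libraries the share with a correlation at least as high was 0.237, 0.261 and 0.087. With the WD libraries split so that no control was shared, the mean over 20 splits was 0.164, 0.0577 and 0.239.

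**Figure D3:**
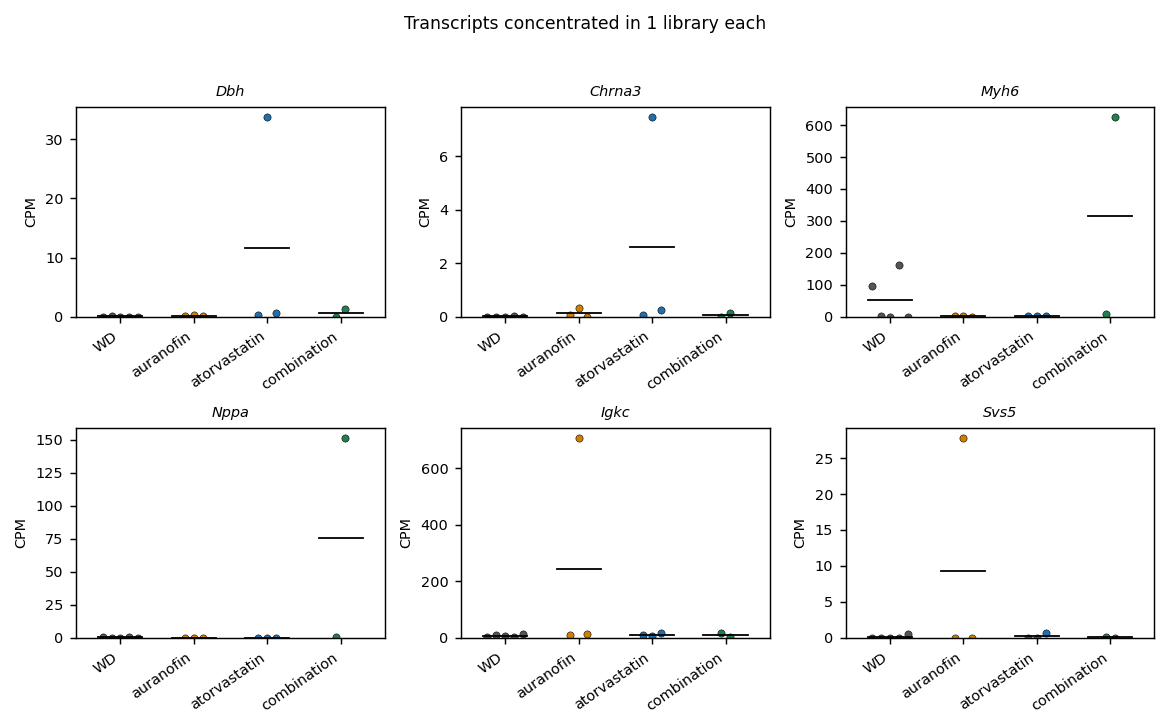
CPM of 6 genes, chosen after their values were seen, in each of the 13 aorta libraries, by group; points are libraries and bars are group means. Dbh reached 33.8 CPM in atorvastatin 2, Nppa 151 CPM in combination 2 and Igkc 707 CPM in auranofin 2, against at most 1.32, 0.322 and 17.8 CPM in any other library.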

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

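The 3 tests of what lies behind the auranofin lists, and the test of lists for the interaction, were chosen after the results were seen.

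Among the 5 WD libraries, 3 values stood apart from the rest of their group out of 60 tested, and chance alone gives about 1 in 20. Insig1, which holds back the cholesterol-sensing SREBP proteins, was highest in WD 3, with a gap of 0.755 of the group's range (log2 CPM 6.36 against 4.97 next). Apoe was lowest in the same library, with a gap of 0.828 (2.65 against 3.88). Myh11, the myosin of contractile smooth muscle, was lowest in WD 2, with a gap of 0.713 (9.71 against 11.42). Each gap lies above the critical value of Dixon for 5 samples.

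The effect of the combination differed from the sum of the drugs for 5 lists by camera with the preset correlation: B cells at −1.39, endothelial cells at −0.62, brown adipocytes at −1.22, fatty acid synthesis at −1.09 and striated muscle at 2.48. None of these 5 passed with an estimated correlation (smallest adjusted p 0.958) or without auranofin 2.

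The 15 lists that passed between auranofin and WD could stem from 1 library, from fat carried along with the aorta, from the drug or from chance. None passed camera with an estimated correlation (smallest adjusted p 0.519). Of 56 splits of these libraries, the real one included, 26 gave at least 15 lists. Only 6 of the 15 stayed past camera without auranofin 2, which is consistent with a large part coming from 1 library, auranofin replicate 2. Fat as the cause could not be decided by the adipocyte score as covariate. With it, 10 of the 12 lists other than the fat and fatty acid lists stayed past camera. Brown adipocytes also stayed past camera with it (0.57, camera adjusted p 0.000409), so it did not take out all signal of fat. The general adipocyte score was 6.28 to 6.81 with auranofin and 4.52 to 6.21 in WD, without overlap. An effect of auranofin treatment remains open as well: 12 of the 15 had the same sign in the combination against atorvastatin, a contrast that shares no library with the first, though these signs were not tested and the lists are not independent of each other. The 3 with the other sign were endothelial genes, fatty acid synthesis (0.97 against −0.12) and cell cycle (−0.27 against 0.06), and the last 2 are among the 6 lists that stayed past camera without auranofin 2. These signs do not speak for the drug in all 9 lists lost without auranofin 2: endothelial genes had a mean of −0.10 in that contrast against 0.52. Without that library the means of interferon-stimulated genes (−0.09), oxidative phosphorylation (−0.07) and contractile smooth muscle genes (0.04) lay on the other side of 0. Among the 12, B cell genes had a mean of only 0.07 in that contrast. Their group mean score was lower in the combination than with atorvastatin (0.28 against 0.31), so their sign depended on the measure. The combination had 2 libraries, and combination 2 had the highest general adipocyte score of all, 7.19. Combination 1 alone was below the atorvastatin mean score for brown adipocytes (3.89 against 4.80), general adipocytes (4.89 against 5.82) and oxidative phosphorylation (6.42 against 6.52). It was above that mean for immediate early genes (6.60 against 6.14). In these lists the sign was opposite to auranofin against WD, while the others of the 12 kept theirs.

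Atrial heart muscle transcripts were high in the combination group, and with them the striated muscle list. In 12 heart muscle markers not looked at before, combination 2 had a median log2 ratio of 3.46 to the other libraries, with 11 of 12 higher, which suggests heart tissue in 1 library. Combination 1 had −0.28 on the same markers, which argues against the combined treatment. In combination 2 Myh6 stood at 625 CPM, Actc1 at 315, Myl4 at 217, Tnnt2 at 188 and Nppa at 151, while the marker Hspb7, at 283 CPM, was exceeded in other libraries. Heart markers were also raised in WD 1 (1.69) and WD 4 (1.82), 2 libraries with no drug.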

How the results depend on the processing

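The settings without 3 libraries (auranofin 2, atorvastatin 2 and combination 2), the exact permutation of list scores and the lists for the interaction and between the 2 drugs were chosen after the data were seen.

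The count of single genes was 0 in all 9 comparisons in edgeR with median-of-ratios size factors, with a stricter low-count filter, with an adipocyte score as covariate and without the 3 libraries, and in limma voom with quality weights. In edgeR without the 3 libraries, 240 (auranofin against WD), 600 (atorvastatin against WD) and 113 (combination against WD) had an unadjusted p under 0.05. With no low-count filter 13 genes passed for auranofin against WD, 2 for atorvastatin against WD, 9 for the combination against WD and 3 for the combination against atorvastatin. Those for auranofin were Marco, Jchain and immunoglobulin genes, such as Igkc at 707 CPM in auranofin 2 and at most 17.8 elsewhere. Those for atorvastatin were Scg2 and Dbh, the latter at 33.8 CPM in atorvastatin 2 and at most 1.32 elsewhere. For the combination they included Nppa, Bmp10 and Myl4, with Nppa at 151 CPM in combination 2 and at most 0.322 elsewhere. DESeq2 passed 2 for auranofin against WD, 4 for the combination against WD, 5 for the combination against atorvastatin, 3 for the combination against auranofin, 5 for auranofin against atorvastatin and 11 for the interaction; the cause was not tested. Leaving out 1 library gave 0 to 10 for the combination against WD, 0 to 8 against atorvastatin, 0 to 8 against auranofin and 0 to 2 for the interaction.

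Lists past camera fell to 0 with an estimated correlation and to 0 with fry in all 7 comparisons tested. By exact permutation it was 0 in the 3 with WD, but there the smallest p possible before adjustment over 32 lists was 0.0179 for each drug and 0.0476 for the combination, so that a list could pass only if many stood at that limit together. Without the 3 libraries the count was 8 for auranofin against WD (6 of the 15 kept), 13 for the combination against WD (1 of 4 kept) and 11 for the auranofin term (11 of 18 kept). With the adipocyte score as covariate it was 7 for the combination. Leaving out 1 library gave 7 to 19 for auranofin, 4 to 10 for atorvastatin, 4 to 13 for the combination and 1 to 10 for the interaction. The cause was not tested.

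The replicate numbers do not pair the libraries: of 15 pairs with the same number 5 correlated above 0.1, over a range of −0.309 to 0.433, and 3 of 11 libraries lay closest to their own number. With the replicate number as block, 0 genes passed in all 9 comparisons, and the lists past camera were 16 for auranofin, 8 for atorvastatin, 7 for the combination, 23 for the auranofin term, 13 for the atorvastatin term and 9 for the interaction.

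Some lists changed direction, and the cause was not tested. For oxidative phosphorylation, auranofin versus WD, the mean was −0.076 with the adipocyte score as covariate, −0.061 without the 3 libraries and −0.065 to 0.42 on leaving out 1. For interferon-stimulated genes, auranofin versus WD, it was −0.087 without the 3 and −0.090 to 0.55 on leaving out 1, and for cell cycle, auranofin versus WD, −0.47 to 0.0024. For brown adipocytes, combination versus WD, it was −0.12 without the 3 and −0.11 to 2.14 on leaving out 1, and for fatty acid synthesis, combination versus WD, −0.21 and −0.21 to 1.44. In the auranofin factor, endothelial cells had −0.036 without the 3 and 0.0018 to 0.40 on leaving out 1, oxidative phosphorylation −0.059 without the 3, and cell cycle −0.25 to 0.023 on leaving out 1.

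Correlations between the comparisons fell from 0.536, 0.494 and 0.659 to 0.164, 0.0577 and 0.239 when no WD library was shared, which by construction removes the shared controls. Of 855 fitted values of named genes, 99 changed sign without the 3 libraries, 47 with voom weights, 13 with the block, 11 with the adipocyte covariate, and 130 on leaving out some 1 library. No scaling moved the median of all genes by more than 0.1. A change of 2-fold was mostly below what this design finds, with 0.5% recovered in simulated data for auranofin against WD.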

Other observations

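The tests on splits of the samples, on the share of variance and on nerve markers were set out before their values were seen. The reading of Foxs1, the transcripts of other tissues and Mt2 was chosen after the values were seen.

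Foxs1, a forkhead transcription factor, was lower in every library with auranofin than in any library without it. It ran from 3.43 to 9.94 CPM in the 5 libraries with auranofin, alone or combined, and from 12.8 to 42.4 CPM in the 8 without it. Because it was picked for this gap, the gap is not a test, and its edgeR adjusted p over all genes was 0.998 in the additive model.

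Several transcripts of other tissues sat in 1 or 2 libraries. Auranofin 2 held Jchain at 134 CPM, Ighg2c at 151 and the seminal vesicle proteins Svs4 and Svs5 at 20.5 and 27.8, against at most 3.23, 7.49, 0.504 and 0.672 elsewhere. Combination 1 held the platelet genes Itga2b at 25.7 and Treml1 at 4.81. Auranofin 3 and WD 3 held the fast skeletal myosin Myh4 at 36.9 and 31.3, and auranofin 1 and WD 3 held Rag1, a recombinase of immature lymphocytes, at 6.67 and 4.05. Col2a1, the collagen of cartilage, was spread more widely. It was at 681 CPM in atorvastatin 2, 363 in WD 1, 236 in combination 2 and 102 in auranofin 3, with a median of 41.0. Whether it came from the aorta or from another tissue was not tested. Mt2 was counted at 0.204 to 2.70 CPM while its neighbour Mt1 stood at 56.1 to 462, so Mt2 values are best treated as uncertain.

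Sympathetic neuron transcripts were high in the atorvastatin group. On 17 markers not looked at before, atorvastatin 2 had a median log2 ratio of 4.28 to the other libraries, with 17 of 17 higher, which suggests nerve tissue in 1 library. The lower of atorvastatin 1 and 3 had −0.17, which argues against atorvastatin treatment as the source of the level in atorvastatin 2. Against the other 12 libraries, atorvastatin 1 had −0.35 with 4 of 17 higher and atorvastatin 3 had 0.19 with 10. Combination 1 had −0.06 with 7 higher and combination 2 had 0.30 with 11. WD 2, given no drug, had 0.78 with 12 higher. Combination 2 held Dbh at 1.32 CPM and Th at 2.08, the second highest values of both. In atorvastatin 2 Slc6a2 stood at 40.6 CPM, Dbh at 33.8 and Th at 17.9. Of the abundant markers, Tubb3 at 26.7 CPM was highest there, while Uchl1 at 60.4 was exceeded in several libraries and Stmn2 at 24.8 in auranofin 2.

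The hypothesis that treatment group sets the list scores was tested by the share of their variance that lay between the 4 groups. The median over 32 lists was 23.4%, against 22.4% when libraries were relabelled (95% of relabellings 10.9% to 39.3%), with a one-sided permutation p of 0.450 over 100000 permutations. The highest share was 47.0% for T cells and the lowest 2.65% for NF-kB inflammatory genes. For the median list most of the variance thus lay between aortas of the same group.

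Chance could not be excluded for the counts of auranofin against WD. Of the 56 splits of these libraries, 25 gave at least as many genes at an unadjusted p under 0.05 as the real 1173 (highest other 7073), and 26 gave at least as many lists as the real 15 (highest other 21). For atorvastatin against WD the 56 splits gave 8 for the real 2648 (highest other 6977) and 40 for the real 8 lists (highest other 23), and chance could not be excluded either. For the auranofin term, 100 splits were drawn, and 43 reached the real 486 (highest other 4807) and 20 the real 18 lists (highest other 25), so chance could not be excluded. For the atorvastatin term 22 of 100 reached the real 1278 (highest other 6156) and 78 the real 9 lists (highest other 23), with the same outcome. Counts at an adjusted p under 0.05 decide nothing here, since the real count was 0 and every split reaches 0: that is 56 of 56 for each drug against WD (highest others 4580 and 3462) and 100 of 100 for each term (highest others 10 and 1). Auranofin and atorvastatin allow 10 splits, too few for a share under 0.05; 2 and 4 of them reached the real 795 genes and 20 lists, where the highest others were 1030 and 22, and all 10 reach the real 0 genes (highest other 0). Of these 20 lists 0 passed with an estimated correlation (smallest adjusted p 0.537).

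The split that called 4580 genes set WD 2, WD 5 and auranofin 2 apart from the other 5 libraries, which points to a structure of the samples. These 3 libraries had the lowest TMM factors of the 13, at 0.639, 0.801 and 0.629, and mitochondrial shares of 26.9%, 24.2% and 38.8%. They do not share a treatment, and the labels give no batch that holds them.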
